A study of Homo sapiens with 18 samples.

How the data were processed

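Transcript levels were measured in primary human aortic smooth muscle cells on Illumina expression arrays, per the labels' protocols. Cells were first held quiescent for 24 h. They were then left untreated, exposed to thrombin at 0.5 units/ml for 2 h or 8 h, exposed to cyclosporin A, or exposed to cyclosporin A with thrombin for 2 h or 8 h. Each of the 6 groups has 3 arrays, and groups and replicate numbers were taken from the sample titles. The labels give neither the dose of cyclosporin A, nor how long each group was exposed to it, nor a vehicle, nor the hour at which untreated cells were collected. Nothing in them says that replicates came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical. Slide, batch and scan date were not given in the sources used here. Per the labels' protocols, total RNA was purified with Trizol and an RNeasy column with DNase treatment, and biotinylated cRNA was made with the Ambion MessageAmp kit.

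The deposited table holds linear probe intensity values for 48803 probes on 18 arrays; the software behind it was not given in the sources used here. All arrays had the same mean intensity, 332, while array medians ran from 98.1 to 126 and the lowest value in the table was 72.7. The values were therefore taken as scaled to a common mean, not normalized in distribution, and not background-subtracted. Because background remains in every value, folds of dim probes are understated. Detection p-values were not used here. For arrays, the number of arrays limits the precision: the fit had 12 residual degrees of freedom before moderation.

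Values were log2 transformed and quantile normalized between arrays with limma 3.58.1 in R 4.3.3. The rule fixed before the data were examined called for quantile normalization unless the array distributions agreed. Equal means could be read as a finished normalization, so the choice between the branches of that rule was made from the array distributions, ahead of any test. The deposited values on a log2 scale without quantile normalization were added as an alternative after the data had been seen.

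Probes were named from the platform annotation supplied with the values. Of 48803 probes, 27578 had 1 gene symbol, 13 had several and 21212 were not listed; a probe that is not listed is unnamed here. Symbols were compared with a current gene table by Entrez identifier for 27541 probes, and 0 symbols changed. A probe was kept if it lay above the median of its array on at least 3 of the 18 arrays. Of 35638 probes that passed, 21471 had 1 symbol, and the probe with the highest mean stood for each gene. This left 15554 genes, of which 4350 had several passing probes; probes of a named gene that disagree are given with it. XIST and Y-linked genes are not reported.

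Background was estimated from the mode of the probe means on the log2 scale, 6.69, and from the spread to its left, 0.046. A gene was called near background in a group whose mean was below 6.83, which is 3 spreads above the mode; this bound was chosen after the data had been seen, and 11713 of the tested genes had a mean above it. Where only 1 of 2 compared groups was near background, the fold is given as "at least", with the bound in place of the lower mean.

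Group means of all 18 arrays were fitted together with limma's lmFit and eBayes. The 10 contrasts were thrombin against control at each time, 8 h against 2 h, cyclosporin A against its counterpart at each of 3 thrombin states, thrombin within cyclosporin A at each time, and the interaction at each time. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment within the contrast. Named genes followed a fixed rule: the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups (for interactions, among called genes), up to 4 members of each gene list with the smallest p, and 13 genes set in advance. Those 13 were F2R, F2RL1, F2RL2, F2RL3, RCAN1, NFATC1, NFATC2, PPIA, LMCD1, CDC6, IL33, HBEGF and CCND1; F2RL1 and PPIA had no tested probe.

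Gene lists were also fixed in advance. Some lists share genes, so their shifts are not independent of each other. Of 32 lists, the 30 with at least 4 tested genes were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the lists of a contrast. Alternatives were camera with an estimated correlation and fry. The lists cover early transcription factors, signalling feedback, calcineurin and NFAT, cytokines, growth factors, NF-kB, YAP/TEAD, contractile, actin, matrix, protease and coagulation genes, cell cycle and its inhibitors, ribosome biogenesis, stress, sterol, hypoxia, TGF-beta, interferon, Notch and G protein genes, and markers of other cell types. Markers of epithelial cells and of platelets and red cells had under 4 tested genes and were not tested.

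The thrombin response with cyclosporin A was set against the response without it by a regression slope through 0 across genes called in either. These responses share no arrays. Data simulated 100 times with equal effects in both arms gave the slope that selection and noise alone produce. The overlap of the 2 h and 8 h responses, which share control arrays, was set beside the overlap of independent lists and beside simulated unchanged groups.

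The code was tested on simulated data for 8 h thrombin against control over 15554 genes. At a log2 change of 0.25, 29 of 50 altered genes were recovered; at 0.5, 1 and 2, 50 of 50 were recovered at each size. There were 18 false calls among 15354 unaltered genes, and of 30 lists the 1 shifted list was called with 0 others. A slope of 0.5 came back as 0.463, 100 of 100 shared genes were recovered, and there were 0 false interaction calls.

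Alternatives planned in advance were scaling to the 75th percentile, no filter and a stricter filter, the mean of a gene's probes, an offset of 32 before log2, a trended and robust variance, only the arrays of a contrast, the replicate number as a block, a fold of at least 2, and leaving out each array in turn. Those added after the data had been seen were the values as deposited, normexp background correction with an offset of 50, a filter on the background bound, and a fit without the 3 arrays of 8 h thrombin alone. Figures were drawn with matplotlib 3.10.9.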

Results

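The series asks which genes thrombin induces at 2 h and 8 h in human aortic smooth muscle cells, and how the response differs in the presence of cyclosporin A. Thrombin is a coagulation protease that signals through protease-activated receptors, and cyclosporin A is an inhibitor of the phosphatase calcineurin, which activates the NFAT transcription factors. The data comprise 18 arrays in 6 groups of 3. Changes below are log2 fold changes ± SE from limma with n = 3 arrays per group unless a fold is stated, and levels are log2 intensities. Each SE is moderated and rests on the spread within all 6 groups, not only within the groups compared.

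Arrays of the same group correlated at 0.996 to 0.998 across genes. Arrays of different groups correlated at 0.983 to 0.995, except that the 3 arrays of 8 h thrombin alone correlated at 0.948 to 0.962 with all others. On the first principal component, which held 56.1% of the variance, those 3 arrays scored 43.7 to 43.9 and the other 15 scored -13.5 to -2.6. On the next component, with 18% of the variance, cyclosporin A alone and cyclosporin A with 8 h thrombin scored 13.5 to 17.2. Control, 2 h thrombin and cyclosporin A with 2 h thrombin scored -13.9 to -6.2. By limma's camera, which sets a list against all other genes, markers of other cell types were not called as lists in any of the 10 contrasts: in 8 h thrombin against control it gave adjusted p = 0.458 for 8 endothelial genes (1 rose, 0 fell), 0.671 for 9 macrophage and leukocyte genes (0 rose, 1 fell) and 0.635 for 5 adventitial fibroblast genes (0 rose, 1 fell), with the same counts adjusted over the list alone. Limma's fry, which tests each list by itself, called all 3 lists there, with adjusted p = 4.28e-06, 0.00352 and 0.00289, and also called the fibroblast list in cyclosporin A alone (adjusted p = 0.000128), among other contrasts. Single members did move, among them the endothelial receptor gene TEK, which rose by 0.84 ± 0.064 at 8 h, and the macrophage marker CD68, which changed by -0.51 ± 0.061 (-0.20 and -0.19 on its other probes). The fibroblast marker CFD changed by -0.48 ± 0.075. In control CD68 stood at 11.81, TEK at 8.76 and CFD at 7.92, and which cells expressed them was not tested.

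**Figure D1:**
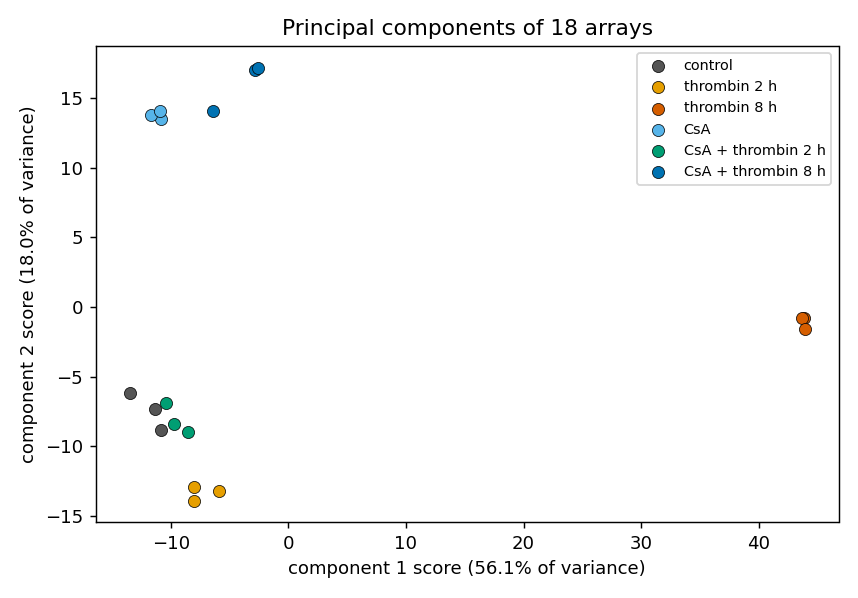
Scores of the 18 arrays on the first 2 principal components of the normalized log2 intensities, coloured by group, with 3 points per group. The 3 arrays of 8 h thrombin alone score 43.7 to 43.9 on component 1, and the other 15 score between -13.5 and -2.6.

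After 2 h of thrombin, the largest rises were in genes of the early transcriptional response. FOSB, an AP-1 transcription factor gene, rose by 4.08 ± 0.157 (16.9-fold), the nuclear receptor gene NR4A2 by 3.57 ± 0.169, the MAP kinase phosphatase gene DUSP1 by 3.52 ± 0.139 and the secreted matricellular gene CCN1 by 3.50 ± 0.165. CXCL8, encoding interleukin 8, rose by 2.52 ± 0.272 and the kinase gene MAP3K8 by 2.41 ± 0.067. Control arrays varied more for some of these genes, with an SD of 0.54 for FOSB, 0.61 for CCN1 and 0.82 for CXCL8. After 2 h of thrombin these SDs were 0.12, 0.06 and 0.19. For NR4A2 the control SD was the lower, at 0.14 against 0.39. RCAN1, a calcineurin-regulating gene that is itself a target of NFAT, rose by 1.94 ± 0.093, though its other probes gave 0.63 and 0.02. Among falls were SNAI2, a transcriptional repressor gene, at -2.03 ± 0.103, and TXNIP, encoding a thioredoxin-binding protein, at -1.93 ± 0.112. The receptor gene F2R, encoding PAR1, stood at 14.52 in control and differed by 0.05 ± 0.068 (adjusted p = 0.804 in limma).

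Of 22 immediate-early transcription factors tested, 15 rose and 0 fell, or 16 and 1 adjusted over the list alone; SRF rose by 1.96 ± 0.092 and ATF3 by 1.84 ± 0.076. The shift had camera adjusted p = 5.44e-29, and adjusted p = 0.0093 with an estimated correlation (both limma). Among 20 NFAT-responsive genes, 11 rose and 0 fell, with the same counts adjusted over the list alone (limma camera adjusted p = 8.13e-19, and adjusted p = 0.00264 with an estimated correlation); PTGS2, encoding cyclooxygenase 2, rose by 2.26 ± 0.145 and IL6 by 1.60 ± 0.109. Among 17 calcineurin and NFAT pathway components, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. Besides RCAN1 these included NFATC1 at 0.93 ± 0.081, whose other probes gave 0.02 to 0.21 (limma camera adjusted p = 0.00104, and adjusted p = 0.0298 with an estimated correlation). NF-kB feedback and target genes rose in 6 of 15 with 0 falls, the same adjusted over the list alone, among them NFKBIA at 1.43 ± 0.081 and NFKBIZ at 2.19 ± 0.133, the latter with -0.02 on its other probe (limma camera adjusted p = 1.02e-06, and adjusted p = 0.0263 with an estimated correlation). YAP/TEAD targets rose in 7 of 18 with 0 falls, again the same adjusted over the list alone, including CCN2 at 1.60 ± 0.124 and LATS2 at 0.92 ± 0.067 (limma camera adjusted p = 1.56e-08, and adjusted p = 0.0103 with an estimated correlation). Regulators of G protein signalling rose in 5 of 12 with 0 falls, also when adjusted over the list alone, among them RGS4 at 2.16 ± 0.136 and the small GTPase gene GEM at 1.86 ± 0.106, with 1.83 and 0.64 on its other probes (limma camera adjusted p = 1.8e-07, and adjusted p = 0.0103 with an estimated correlation). Of 13 TGF-beta and BMP response genes, 6 rose and 2 fell, likewise adjusted over the list alone: ID2 rose by 1.02 ± 0.068, while ID1 changed by -0.73 ± 0.093, and by -0.07 on its other probe. That shift was called with the preset correlation only (limma camera adjusted p = 6.63e-05, but adjusted p = 0.071 with an estimated correlation). Several of these lists share genes, so their shifts are not separate findings. The NFAT-responsive list shares NR4A2 with the immediate-early list and PTGS2 with the NF-kB list. It shares RCAN1 and NFATC1 with the pathway components.

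At 2 h, limma called 1623 of 15554 genes, 862 higher and 761 lower, of which 64 and 7 changed at least 2-fold. The balance of directions depended on the scaling: 53.1% of calls were higher in the main setting, 77.7% of 1302 calls after scaling to the 75th percentile, and 68.4% of 1382 calls with values as deposited.

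After 8 h of thrombin, a different set of genes led. HAS2, encoding a hyaluronan synthase, rose by 4.78 ± 0.095 (27.5-fold), the chemokine gene CCL2 by 4.45 ± 0.200 (21.9-fold), the growth factor gene BMP2 by 4.36 ± 0.068 and PTGS2 by 4.24 ± 0.145. LMCD1, a LIM-domain protein gene, rose by 4.15 ± 0.066 (17.7-fold), IL6 by 3.92 ± 0.109 and the cytokine gene IL33 by 3.32 ± 0.158. The cyclin D1 gene CCND1 rose by 2.13 ± 0.072, and HBEGF, a ligand of the EGF receptor, was near background in control and at least 2.75-fold higher. Among falls were SLC40A1, encoding the iron exporter ferroportin, at -4.22 ± 0.101, the phosphodiesterase gene PDE5A at -3.59 ± 0.097 and CYP1B1, a cytochrome P450 gene, at -3.42 ± 0.084. KLHL24 was near background in thrombin and at least 9.33-fold lower. Other probes of several of these genes changed much less: 0.30 to 1.07 for HAS2, 0.28 for IL33 and -0.25 to -0.13 for PDE5A. F2R differed by 0.06 ± 0.068 (limma adjusted p = 0.54), but its other probe gave -0.34, and the mean of its probes fell by 0.14 on the log2 scale (limma adjusted p = 0.0295).

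Gene groups moved together at 8 h. All 22 ribosome biogenesis genes rose, also when adjusted over the list alone, with a median of 1.22 and with NOP2 at 1.71 ± 0.069 (0.79 on its other probe) and RRS1 at 1.68 ± 0.068 (limma camera adjusted p = 6.65e-17, and adjusted p = 0.0028 with an estimated correlation). Of 32 G1/S and DNA replication genes, 25 rose and 2 fell, the same adjusted over the list alone; UHRF1 rose by 2.75 ± 0.073 and FEN1 by 1.54 ± 0.056 (limma camera adjusted p = 1.81e-09, and adjusted p = 0.00482 with an estimated correlation). By contrast, 24 G2/M and mitosis genes split into 6 higher and 7 lower, also when adjusted over the list alone, with limma adjusted p = 0.807 for the shift. Hypoxia and glycolysis genes rose in 15 of 17 with 1 fall, the same adjusted over the list alone, including the glucose transporter gene SLC2A1 at 2.23 ± 0.085 and LDHA at 1.54 ± 0.066 (limma camera adjusted p = 1.81e-09, and adjusted p = 0.00443 with an estimated correlation). Of 20 actin cytoskeleton and focal adhesion genes, 17 rose and 0 fell, or 17 and 1 adjusted over the list alone, led by the integrin gene ITGA5 at 2.13 ± 0.067 (limma camera adjusted p = 1.95e-07, and adjusted p = 0.00845 with an estimated correlation). Growth factor genes rose in 14 of 26 and fell in 3, or 14 and 4 adjusted over the list alone, with BDNF at 2.26 ± 0.075, but 0.05 to 0.39 on its other probes, beside BMP2 (limma camera adjusted p = 0.000373, and adjusted p = 0.0141 with an estimated correlation).

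Of 22 ATF4 and amino acid response genes, 18 fell at 8 h and 2 rose, the same adjusted over the list alone; TRIB3 changed by -2.59 ± 0.078, DDIT3 by -1.63 ± 0.068 and the serine synthesis gene PSAT1 by -1.54 ± 0.056 (limma camera adjusted p = 9.17e-09, and adjusted p = 0.0136 with an estimated correlation). Of 20 CDK inhibitors and antiproliferative genes, 15 fell and 2 rose, also adjusted over the list alone, among them TP53INP1 at -1.77 ± 0.076 and BTG1 at -1.59 ± 0.075 (limma camera adjusted p = 2.58e-06, and adjusted p = 0.0136 with an estimated correlation). Cytokines and chemokines rose in 12 of 20 and fell in 1, or 13 and 1 adjusted over the list alone, and NFAT-responsive genes rose in 10 of 20 and fell in 1, the same adjusted over the list alone. For cytokines limma camera gave adjusted p = 2.07e-05, but adjusted p = 0.133 with an estimated correlation. For NFAT-responsive genes it gave 4.13e-05, but adjusted p = 0.0655 with an estimated correlation (limma). Of 27 extracellular matrix genes 16 fell and 7 rose, the same adjusted over the list alone, with a median of -0.28 against a mean of 0.08, and a downward shift in the test that was not called (limma camera adjusted p = 0.365). THBS1, encoding thrombospondin 1, rose by 1.64 ± 0.096. Matrix proteases and inhibitors split into 6 higher and 4 lower of 14, likewise adjusted over the list alone (limma adjusted p = 0.387); TIMP3, encoding a metalloproteinase inhibitor, rose by 2.42 ± 0.092.

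In all, 7248 of 15554 genes passed limma's threshold at 8 h, 3408 higher and 3840 lower, with 392 and 352 changed at least 2-fold. Replicate arrays of a group lay close together, so small changes were called.

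**Figure D2:**
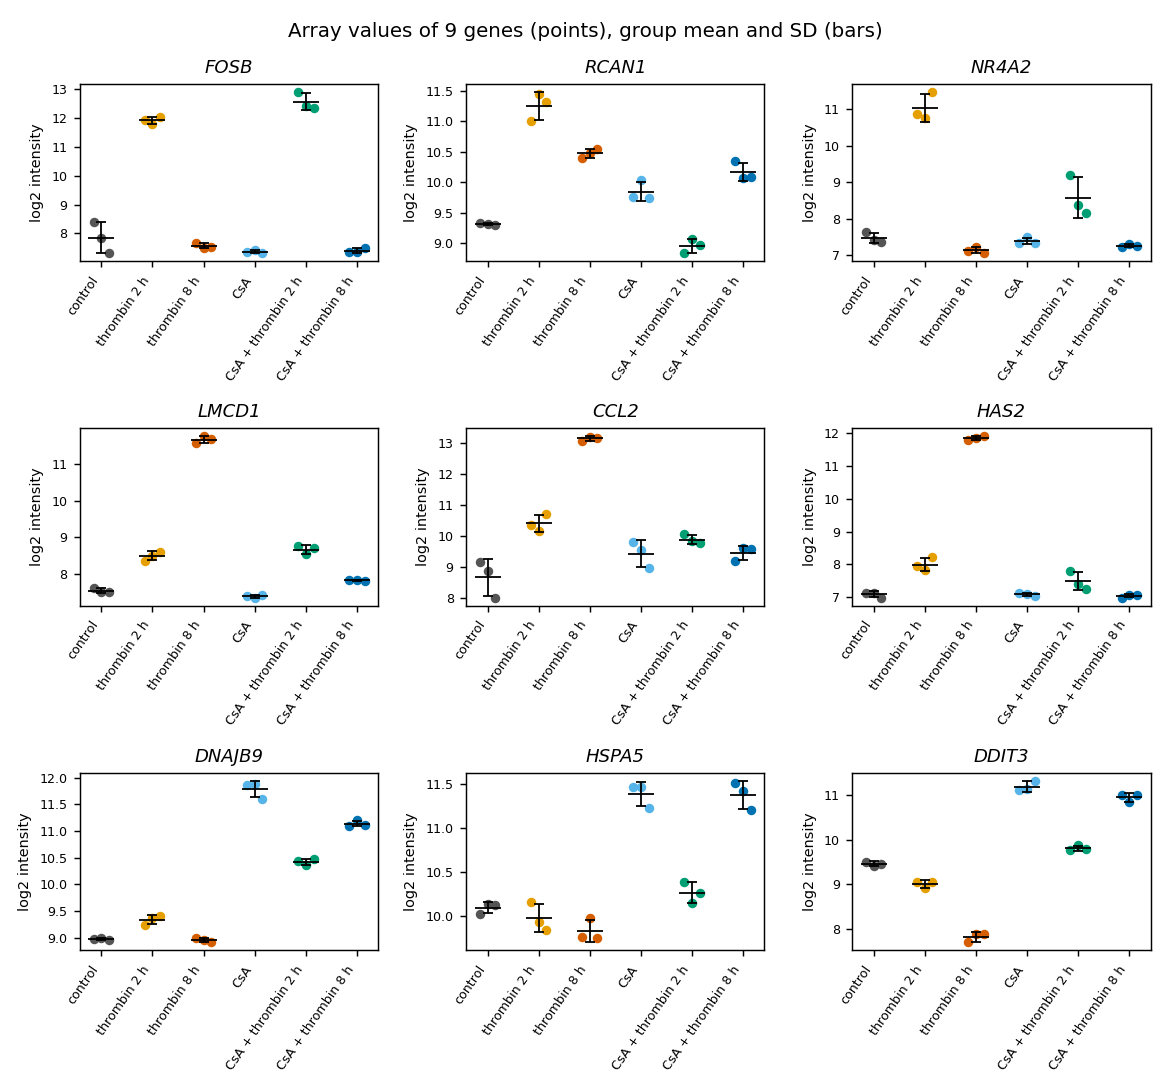
Log2 intensity of 9 genes on each array (points), with the mean and SD of the 3 arrays of each group (bars); each panel has its own vertical axis, which does not start at 0. LMCD1, CCL2 and HAS2 are highest after 8 h of thrombin without cyclosporin A, and DNAJB9 is highest in cyclosporin A alone, at 11.79 against 8.98 in control.

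Comparing the times directly, BMP2 was higher at 8 h than at 2 h by 4.01 ± 0.068, HAS2 by 3.87 ± 0.095 (0.25 to 0.95 on its other probes) and LMCD1 by 3.20 ± 0.066, while FOSB was lower by 4.37 on the log2 scale, at -4.37 ± 0.157, and NR4A2 at -3.90 ± 0.169. The integrin gene ITGA2 was higher at 8 h by 2.79 ± 0.067, and IRS2, an insulin receptor substrate gene, changed by -2.98 ± 0.076. Of 22 immediate-early factors 15 were lower and 3 higher at 8 h, the same adjusted over the list alone (limma adjusted p = 6.95e-05, but adjusted p = 0.265 with an estimated correlation). In total 6846 genes differed, 3255 higher and 3591 lower at 8 h (limma). Higher genes made up 47.5% of these, 48.4% of 7249 after scaling to the 75th percentile and 55.9% of 7760 as deposited. Called genes of both times overlapped by 513 raised and 545 lowered at both, and 270 went in opposite directions. Independent lists of these lengths would share 188.9 and 187.9, and unchanged groups simulated against the same controls shared at most 1 gene. Unchanged groups give few calls by design, so that value does not show what shared controls add to lists this long. Across genes, the correlation of the changes was 0.369 and their covariance 0.0317. The simulated unchanged groups gave 0.5 and 0.00218. That 0.5 is what shared controls give where nothing changes, so 0.369 cannot be read as less agreement than chance. Genes are not independent replicates. Both comparisons share the 3 controls, which are too few to be split. Without replicate 3 of 2 h thrombin, 685 genes in place of 1058 were called in the same direction at both times.

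Cyclosporin A alone raised genes of endoplasmic reticulum stress. DNAJB9, encoding a chaperone of the endoplasmic reticulum, rose by 2.81 ± 0.065 (7.02-fold), FICD, whose product modifies the chaperone BiP, by 2.19 ± 0.072 and HSPA13 by 1.83 ± 0.127. Of 19 endoplasmic reticulum chaperones and unfolded protein response genes, 14 rose and 0 fell, the same adjusted over the list alone, including MANF at 1.74 ± 0.071 and SDF2L1 at 1.23 ± 0.068 (limma camera adjusted p = 5.27e-15, and adjusted p = 0.00084 with an estimated correlation). Of 22 ATF4 and amino acid response genes, 15 rose and 4 fell, also adjusted over the list alone, with DDIT3 at 1.72 ± 0.068 and the amino acid transporter gene SLC3A2 at 1.18 ± 0.053 (limma camera adjusted p = 3.35e-09, and adjusted p = 0.0302 with an estimated correlation). CCN1 rose by 2.69 ± 0.165, the stress cytokine gene GDF15 by 2.23 ± 0.161 and IL6 went from 7.01 in control to 9.21, so these genes were raised without thrombin. Sterol synthesis genes rose in 9 of 16 with 1 fall, or 10 and 1 adjusted over the list alone, among them CYP51A1 at 0.81 ± 0.089 and SQLE at 0.60 ± 0.058 (limma camera adjusted p = 0.000551, but adjusted p = 0.1 with an estimated correlation). Falls included SLC40A1 at -1.66 ± 0.101, MN1 at -1.55 ± 0.082 and AXIN2, a Wnt feedback gene, at -1.28 ± 0.087. Genes listed as markers of other cells moved beside these groups. PDGFRA (fibroblasts) changed by -0.45 ± 0.065, with -0.83 on its other probe, and CFD by -0.30 ± 0.075. CD68 changed by -0.34 ± 0.061, with -0.25 and 0.18 on its other probes. CD14 (monocytes) changed by 0.20 ± 0.062, a call lost without replicate 2 or 3 of control or of cyclosporin A. In control PDGFRA stood at 13.24 and CD68 at 11.81, against 7.92 for CFD and 7.27 for CD14. Which cells expressed them was not tested. RCAN1 rose by 0.53 ± 0.093, with 0.10 and -0.01 on its other probes, and LMCD1 differed by -0.15 ± 0.066 (limma adjusted p = 0.1).

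With limma, 4153 genes differed between cyclosporin A and control, 1919 higher and 2234 lower, and 58 and 26 changed at least 2-fold. Higher genes made up 46.2% of these calls, 35.4% of 3874 calls after scaling to the 75th percentile and 55.6% of 4079 with values as deposited.

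At 2 h of thrombin, cells with cyclosporin A had lower levels of NR4A2, at -2.46 ± 0.169, and of RCAN1, at -2.30 ± 0.093 (4.93-fold), than cells without it. RCAN1 stood at 11.25 in thrombin and 8.95 in cyclosporin A with thrombin, below its control level of 9.32. RGS2, a regulator of G protein signalling, changed by -1.59 ± 0.115 and IL6 by -0.87 ± 0.109. Of 20 NFAT-responsive genes, 6 were lower and 0 higher, or 7 and 1 adjusted over the list alone; camera with its preset correlation called the shift (limma adjusted p = 0.00021), but adjusted p = 0.453 with an estimated correlation. Not all genes of this kind differed: LMCD1 gave 0.17 ± 0.066 (limma adjusted p = 0.111) and NFATC1 -0.18 ± 0.081 (limma adjusted p = 0.187), the latter passing the threshold after scaling to the 75th percentile, with values as deposited, and without replicate 2 of 2 h thrombin. LMCD1 passed it without replicate 3 of 2 h thrombin or replicate 2 of cyclosporin A with 2 h thrombin. Higher genes included PPP1R10, encoding a phosphatase regulatory subunit, at 1.16 ± 0.078, DNAJB9 at 1.08 ± 0.065 and DDIT4, a stress-induced inhibitor of mTORC1, at 1.01 ± 0.097. RCAN1's other probes gave -0.77 and -0.18. LBH changed by -1.25 ± 0.067, with -0.10 to 0.02 on its other probes.

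The number of genes in this comparison cannot be read without the scaling. In the main setting limma called 1297 genes, 561 higher and 736 lower; after scaling to the 75th percentile it called 4597, 1090 higher and 3507 lower, and with values as deposited 6852, 4680 higher and 2172 lower. Higher genes thus made up 43.3%, 23.7% and 68.3% of calls, and without replicate 2 of cyclosporin A with 2 h thrombin 829 genes were called. At least 2-fold changes were few, with 6 genes higher and 6 lower.

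At 8 h, cyclosporin A with thrombin lay far from thrombin alone. HAS2 was lower by 4.82 on the log2 scale, at -4.82 ± 0.095 (28.3-fold; -1.09 to -0.20 on its other probes), BMP2 at -3.90 ± 0.068, LMCD1 at -3.86 ± 0.066, CCL2 at -3.68 ± 0.200 and PTGS2 at -3.08 ± 0.145. IL33 changed by -2.35 ± 0.158 (-0.17 on its other probe), CCND1 by -2.27 ± 0.072 and HBEGF by -1.44 ± 0.067. LMCD1 reached 11.69 in thrombin and 7.82 in cyclosporin A with thrombin, against 7.54 in control. RCAN1 differed little at this time, at -0.31 ± 0.093 (limma adjusted p = 0.00768). Higher genes were TRIB3 at 3.35 ± 0.078 (10.2-fold), DDIT3 at 3.11 ± 0.068, CYP1B1 at 2.98 ± 0.084 and the lipid droplet gene PLIN2 at 2.68 ± 0.059.

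The groups raised by 8 h of thrombin were lower here. All 22 ribosome biogenesis genes were lower, also adjusted over the list alone, with NIP7 at -1.92 ± 0.073; 15 of 17 hypoxia and glycolysis genes were lower and 0 higher, the same adjusted over the list alone, with SLC2A1 at -2.79 ± 0.085; and 25 of 32 G1/S genes were lower and 2 higher, or 28 and 2 adjusted over the list alone. In limma camera these shifts had adjusted p = 7.67e-19, 1.1e-11 and 4.61e-13, and each had adjusted p = 0.00101 with an estimated correlation. Of 12 thrombin receptor, coagulation and fibrinolysis genes, 8 were lower and 2 higher, or 8 and 3 adjusted over the list alone, with the urokinase receptor gene PLAUR at -1.43 ± 0.067 (limma camera adjusted p = 0.00323, and adjusted p = 0.0195 with an estimated correlation). NFAT-responsive genes were lower in 11 of 20 and higher in 1, also adjusted over the list alone (limma camera adjusted p = 3.06e-05, and adjusted p = 0.0498 with an estimated correlation). MAPK feedback phosphatases and Sprouty genes were lower in 9 of 14 and higher in 1, or 10 and 1 adjusted over the list alone, with SPRY2 at -1.99 ± 0.168 (limma camera adjusted p = 0.000105, but adjusted p = 0.104 with an estimated correlation). Higher were 21 of 22 ATF4 and amino acid response genes with 0 lower, and 14 of 19 endoplasmic reticulum genes with 0 lower, both the same adjusted over the list alone. HSPA5, encoding the chaperone BiP, was among the latter at 1.54 ± 0.088. Limma camera gave adjusted p = 9.21e-18 for the former list and 2.49e-06 for the latter, and adjusted p = 0.00101 and 0.00778 with an estimated correlation. CDK inhibitors and antiproliferative genes were higher in 15 of 20 and lower in 3, or 16 and 3 adjusted over the list alone, CDKN1A at 1.54 ± 0.081 among them, with 0.03 on its other probe (limma camera adjusted p = 6.05e-07, and adjusted p = 0.00778 with an estimated correlation). Beside these groups, TEK changed by -0.87 ± 0.064, PDGFRA by -0.77 ± 0.065 and CD68 by 0.26 ± 0.061, the last with -0.06 and 0.45 on its other probes and not called after scaling to the 75th percentile. In all limma called 6784 genes, 3673 higher and 3111 lower, with 270 and 344 at least 2-fold; higher genes made up 54.1% of calls, 43.5% of 6102 after scaling to the 75th percentile and 63.2% of 7079 as deposited.

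**Figure D3:**
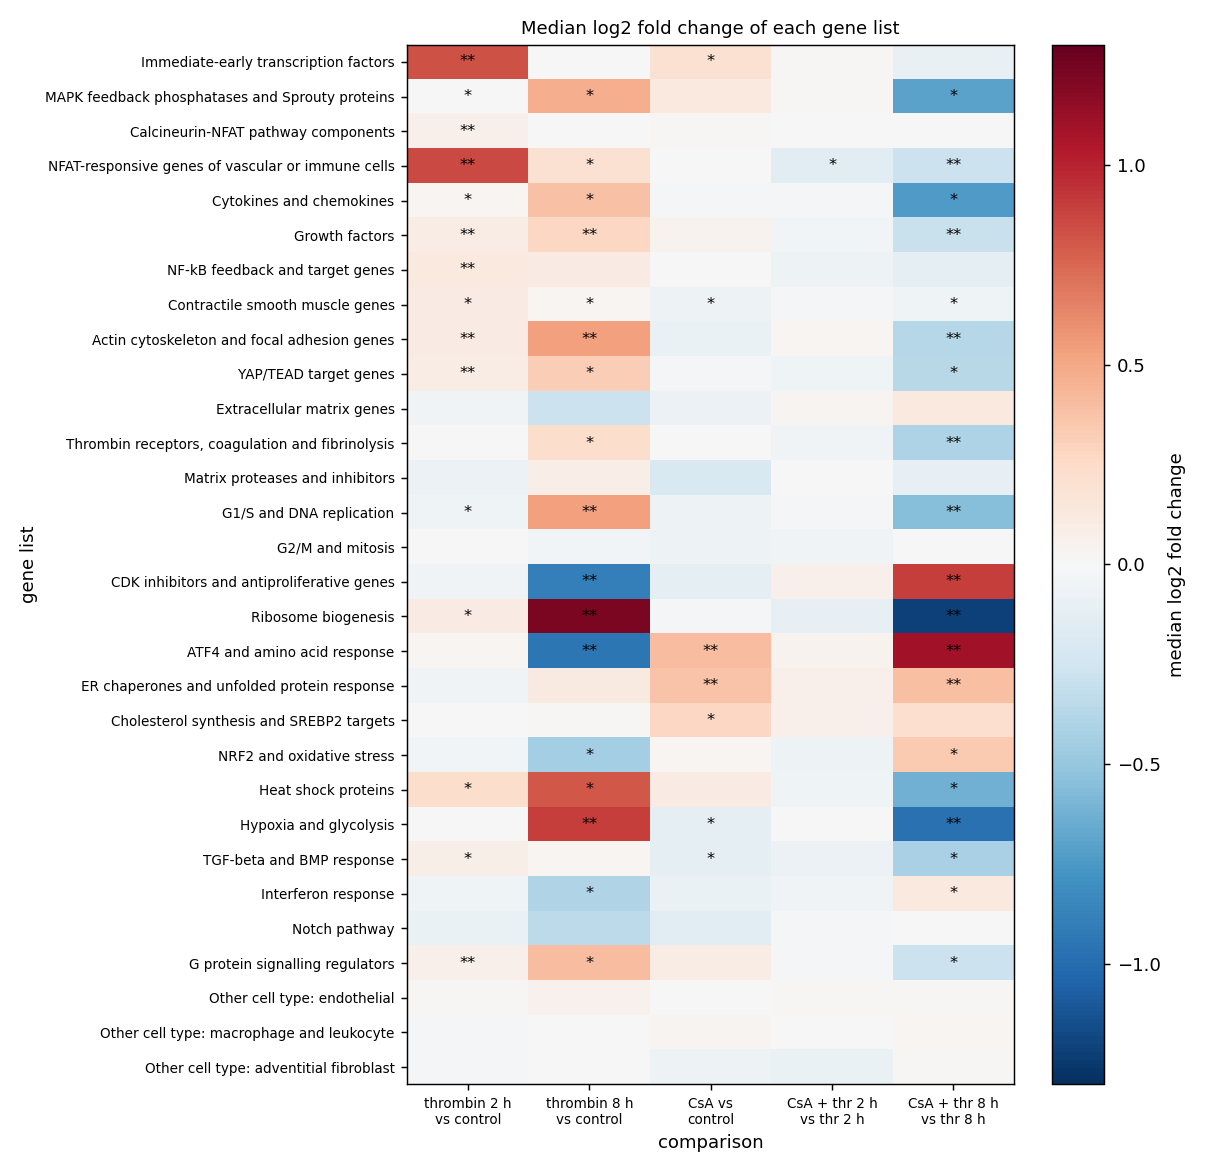
Median log2 fold change of each of 30 gene lists (vertical axis) in 5 comparisons (horizontal axis), red above 0 and blue below; ** marks a list called by camera with both its preset and an estimated correlation and * one called with the preset only. Ribosome biogenesis has a median of 1.22 in 8 h thrombin against control and -1.21 in cyclosporin A with 8 h thrombin against 8 h thrombin.

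Within cyclosporin A, 2 h of thrombin still raised FOSB, by 5.21 ± 0.157 (37.0-fold). WEE1, a kinase gene that restrains entry into mitosis, rose by 2.05 ± 0.074, GEM by 2.05 ± 0.106 (1.94 and 0.67 on its other probes) and LMCD1 by 1.28 ± 0.066. The endothelin gene EDN1 changed by -2.17 ± 0.144, GDF15 by -2.09 ± 0.161, IL6 by -1.47 ± 0.109 and RCAN1 by -0.89 ± 0.093, the last with -0.25 and -0.15 on its other probes. Of 19 endoplasmic reticulum genes, 16 fell and 0 rose, the same adjusted over the list alone, with DNAJB9 at -1.37 ± 0.065 and MANF at -1.35 ± 0.071 (limma camera adjusted p = 4.82e-16, and adjusted p = 0.000608 with an estimated correlation). Of 20 actin cytoskeleton and focal adhesion genes, 10 rose and 1 fell, or 13 and 1 adjusted over the list alone, with ACTN4 at 0.66 ± 0.060 (limma camera adjusted p = 3.11e-06, and adjusted p = 0.0297 with an estimated correlation). ACTN4 had been lowered by cyclosporin A, from 9.27 in control to 8.69, and stood at 9.35 after thrombin. Beside this, CFD differed by 0.26 ± 0.075, CD68 by 0.19 ± 0.061 and CD14 by -0.21 ± 0.062 (-0.02 on its other probe). These calls depended on single arrays: CFD on replicate 3 of cyclosporin A and 2 and 3 of the combined group, CD68 on replicates 1 and 3 of both, and CD14 on replicate 2 of cyclosporin A and 1 of the combined group. Immediate-early factors rose in 12 of 22 and fell in 1, or 15 and 1 adjusted over the list alone (limma camera adjusted p = 2.29e-08, but adjusted p = 0.141 with an estimated correlation). Limma called 3654 genes, 1803 higher and 1851 lower, of which 54 and 29 changed at least 2-fold. The share of higher calls was 49.3%, against 38.8% of 3150 after scaling to the 75th percentile and 38.2% of 3183 as deposited.

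Within cyclosporin A, 8 h of thrombin gave smaller changes. The secreted protein gene CRISPLD2 rose by 1.74 ± 0.116, the heat shock gene HSPA1B by 1.33 ± 0.104, IL33 by 1.18 ± 0.158 (0.10 on its other probe) and the smooth muscle actin gene ACTG2 by 1.14 ± 0.082. EGR1, an early growth response factor gene, changed by -2.27 ± 0.315, EDN1 by -2.07 ± 0.144 and SPRY4 by -1.86 ± 0.186, the last with -0.09 on its other probe. LMCD1 rose by 0.44 ± 0.066. The rise of IL33 differed between arrays, which stood at 11.02, 12 and 12.02 after thrombin against 10.42 to 10.63 in cyclosporin A alone. Actin cytoskeleton genes rose in 9 of 20 with 0 falls, or 10 and 0 adjusted over the list alone, TPM4 at 0.48 ± 0.059 among them (limma camera adjusted p = 4.07e-07, and adjusted p = 0.0324 with an estimated correlation). Contractile smooth muscle genes rose in 7 of 19 with 0 falls, or 8 and 0 adjusted over the list alone, with TAGLN at 0.51 ± 0.078 (0.08 and 0.80 on its other probes) (limma camera adjusted p = 1.04e-05, but adjusted p = 0.0819 with an estimated correlation). In cyclosporin A alone, 8 of these 19 genes were lower than control and 0 higher, the same adjusted over the list alone (limma camera adjusted p = 0.0276, but adjusted p = 0.434 with an estimated correlation). That call was also lost without replicate 1 or 2 of control or replicate 2 of cyclosporin A. MYL9, encoding a myosin light chain, stood at 9.61 in control, 9.22 in cyclosporin A and 9.67 after thrombin. PDGFRA changed by -0.33 ± 0.065 beside these genes. Limma called 2197 genes, 1153 higher and 1044 lower, and 12 and 23 changed at least 2-fold. Higher genes made up 52.5% of calls, and 30.2% of 1575 after scaling to the 75th percentile.

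The interaction asks directly whether the change with thrombin differed with cyclosporin A. At 2 h it was most negative for IL6 at -3.07 ± 0.154, CXCL8 at -2.99 ± 0.384, CCN1 at -2.98 ± 0.234 and RCAN1 at -2.83 ± 0.131, whose other probes gave -0.87 and -0.17. For CCN1 most of this lay in the starting level, 12.01 in cyclosporin A alone and 9.32 in control, against 12.53 and 12.82 after thrombin. CXCL8 started at 12.02 and 10.09, and stood at 11.55 and 12.61 after thrombin. For IL6 the difference holds a higher starting level, 9.21 in cyclosporin A alone and 7.01 in control, as well as a lower level after thrombin, 7.73 against 8.61. For RCAN1, which started at 9.84 and 9.32, most of it lay in the level after thrombin. SNAI2 had an interaction of 2.10 ± 0.145 and TIPARP, a target of the aryl hydrocarbon receptor, of 1.67 ± 0.080. Of 19 endoplasmic reticulum genes, 12 had negative and 0 positive interactions, the same adjusted over the list alone (limma camera adjusted p = 4.17e-14, and adjusted p = 0.00113 with an estimated correlation). NFAT-responsive genes had 7 negative and 2 positive of 20, or 8 and 2 adjusted over the list alone (limma camera adjusted p = 8.85e-05, but adjusted p = 0.16 with an estimated correlation). Cyclosporin A alone had raised 5 of these 20 and lowered 1, with IL6, PTGS2, CXCL8 and RCAN1 among the raised. Camera did not call that shift (limma adjusted p = 0.0892), while fry did (limma adjusted p = 0.0112). Part of the negative interactions thus lies in raised starting levels. There were 2606 genes with an interaction in limma, 1337 positive and 1269 negative; positive ones made up 51.3% of calls, 24.2% of 2252 after scaling to the 75th percentile and 32.4% of 2313 as deposited.

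At 8 h the interaction reached -4.83 ± 0.135 for HAS2 (-1.01 to -0.24 on its other probes), -4.44 ± 0.282 for CCL2, -4.33 ± 0.205 for PTGS2, -4.12 ± 0.096 for BMP2 and -3.71 ± 0.093 for LMCD1. It was 3.26 ± 0.142 for SLC40A1, 3.19 ± 0.119 for CYP1B1 and 2.44 ± 0.111 for TRIB3. RCAN1 had -0.84 ± 0.131, with -0.35 and -0.27 on its other probes. It started at 9.84 in cyclosporin A alone and 9.32 in control. After thrombin its arrays stood at 10.07 to 10.34 with cyclosporin A and 10.39 to 10.55 without it. More of its interaction thus lay in the starting level than in the level after thrombin. PTGS2 started at 10.81 in cyclosporin A alone and 9.56 in control, so part of its interaction lies in the starting level. All 22 ribosome biogenesis genes had negative interactions, also adjusted over the list alone (limma camera adjusted p = 6.27e-19, and adjusted p = 0.00166 with an estimated correlation). NFAT-responsive genes had 12 negative and 1 positive of 20, the same adjusted over the list alone (limma camera adjusted p = 2.35e-06, and adjusted p = 0.0354 with an estimated correlation). Cyclosporin A alone had raised 5 of these 20 and lowered 1, so part of these negative interactions may lie in raised starting levels. In total 5822 genes had an interaction in limma, 3143 positive and 2679 negative; positive ones made up 54.0% of calls, 48.5% of 5220 after scaling to the 75th percentile and 54.2% of 5265 as deposited.

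Across genes called in either arm, the slope of the thrombin change in cyclosporin A on the change without it was 0.449 at 2 h (4385 genes, jackknife SE over arrays 0.093) and 0.118 at 8 h (7717 genes, jackknife SE 0.03). Simulated data with no interaction gave 0.922 to 0.956 at 2 h and 0.958 to 0.974 at 8 h. Of the 1623 genes called at 2 h, 677 (41.7%) had an interaction opposing their change, and 86 had one in the same direction; 639 (39.4%, against 64.0% in simulated data with no interaction) were also called in the same direction in cyclosporin A and 253 in the opposite one. Of the 7248 called at 8 h, 5284 (72.9%) had an opposing interaction and 24 one in the same direction, while 1315 (18.1%, against 80.5% simulated) were called in the same direction in cyclosporin A and 413 in the opposite one.

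**Figure D4:**
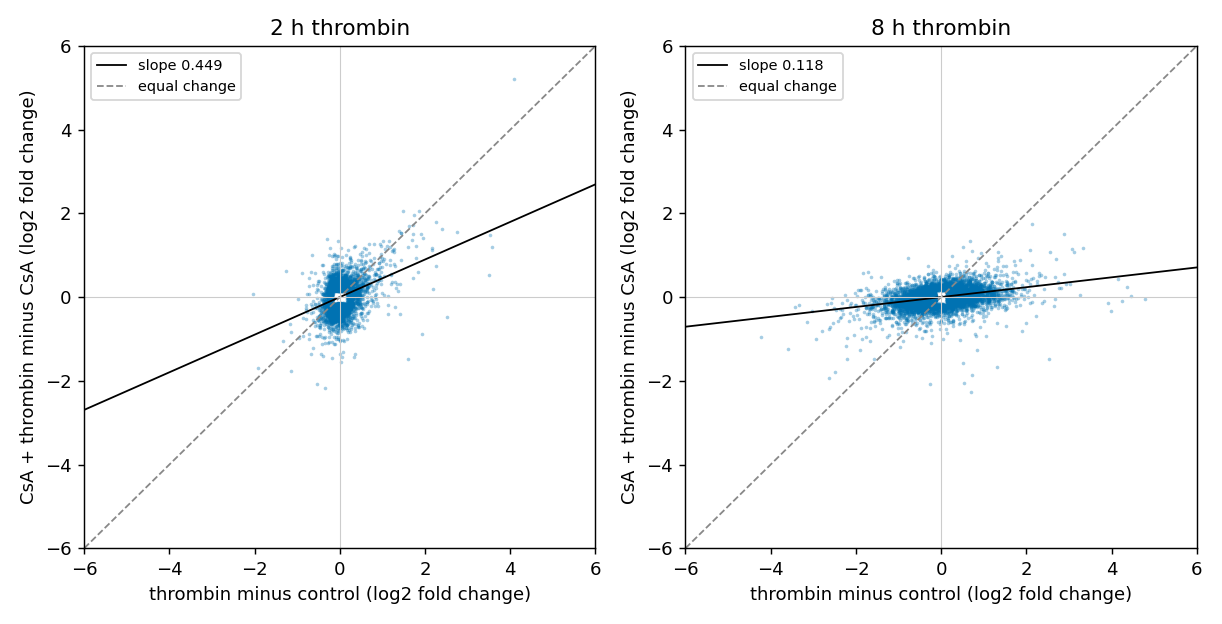
Log2 fold change with thrombin in cyclosporin A (vertical axis) against that without it (horizontal axis), each point a gene called in either, at 2 h (left) and 8 h (right); solid lines are slopes through 0 and dashed lines mark equal change. The slopes are 0.449 at 2 h and 0.118 at 8 h.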

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

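The tests of the separation of the 8 h thrombin arrays and of the weaker cyclosporin A changes at 2 h were written after those results had been seen, as were the breakdowns of the random draws and the background bound; the test of other probes was written before.

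The 3 arrays of 8 h thrombin alone stood out because they lie far from all 15 others, including those of cyclosporin A with 8 h thrombin. Quantile normalization is argued against as the source. With values as deposited, without that step, their highest correlation with an array of another group is 0.962. This lies under 0.982, the lowest between other groups. A scale factor per array leaves a correlation of log2 values unchanged, so the scaling already in the deposited values was not tested. A batch of these 3 arrays, which no label names, was also weighed. Genes called at 8 h kept their direction in 1315 cases and reversed it in 413 with 8 h thrombin in cyclosporin A. With 2 h thrombin in cyclosporin A the counts were 1290 and 1445. That comparison is of another time and may hold a difference in exposure to cyclosporin A, so it cannot count for a batch. On the arrays of cyclosporin A with 8 h thrombin taken singly, 55.1% to 65.1% of genes called at 8 h kept their direction. Each array lay above the 50% set for a batch as the whole cause, but not each above the 60% set to exclude it. A response weakened by cyclosporin A would also lower these shares, so the shortfall from 60% cannot tell that from a batch. As part of the cause a batch cannot be told apart, because it would coincide with the group and lower the slope of 0.118.

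The changes of cyclosporin A alone stood out by being smaller in cyclosporin A with 2 h thrombin, DNAJB9 falling from 11.79 to 10.42. A swap of labels is argued against, since 51 of 64 genes raised at least 2-fold by 2 h of thrombin were higher on all 3 arrays of the combined group than on all 3 of cyclosporin A alone. For the endoplasmic reticulum list as a set, a lasting lowering by thrombin is argued against too. Its median against cyclosporin A alone was -0.44 to -0.36 on the arrays with 2 h thrombin but 0.09 to 0.13 on those with 8 h. At 8 h, 6 of its 19 genes were called higher than in cyclosporin A alone and 1 lower. Single genes did stay lower at 8 h than in cyclosporin A alone: DNAJB9 at 11.1 to 11.2 against 11.61 to 11.89. SPRY4, outside the list, stood at 8.11 to 8.53 against 9.73 to 10.47. Other genes raised by cyclosporin A were not tested as a set. A shorter exposure to cyclosporin A in the 2 h arrays cannot be told apart from a passing effect of thrombin: 17 of 19 list genes were higher on all 8 h arrays than on all 2 h arrays, and exposure is not in the labels. The interaction at 2 h may therefore hold a difference in exposure.

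Other probes of genes that changed at least 2-fold at 8 h stood out by changing less, as for HAS2 and PDE5A. Among 353 such probes of 250 genes, 195 showed less than 50% of the change. Of the 195, 53 (27.2%) lay under the background bound in both groups. That is short of the 50% set for low signal as the main reason. The bound of 6.83 lies close to the background mode of 6.69, and folds of dim probes above it are understated too. This count therefore cannot decide on low signal, which stays open. The genes were also picked by the change on their probe with the highest mean, which favours smaller changes on the others. Transcript variants and probes that miss their target stay open.

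Interactions stood out because they are differences between groups of a difference: limma called 2606 genes at 2 h and 5822 at 8 h, with slopes of 0.449 and 0.118, and 6846 genes differed between the times. At 2 h the values were 2.10 for SNAI2, 1.89 for TAF15, 1.67 for TIPARP, -3.07 for IL6, -2.99 for CXCL8, -2.98 for CCN1, -2.83 for RCAN1 and 0.32 for LMCD1. TAF15 had an SE of 0.448 and 0.32 on its other probe, and missed the threshold with a trended and robust variance (limma adjusted p = 0.0611). The LMCD1 call was lost after scaling to the 75th percentile (limma adjusted p = 0.563) and as deposited (limma adjusted p = 0.34), and without replicate 1 of 2 h thrombin. At 8 h the values were 3.26 for SLC40A1, 3.19 for CYP1B1, 3.14 for KLHL24, -4.83 for HAS2, -4.44 for CCL2, -4.33 for PTGS2, -3.71 for LMCD1, -2.26 for CCND1, -2.14 for IL33, -1.52 for HBEGF, -0.84 for RCAN1 and -0.24 for CDC6. KLHL24 was near background in 8 h thrombin and HBEGF in control, so the values of KLHL24 and HBEGF are not exact. The CDC6 call was lost with values as deposited (limma adjusted p = 0.111) and without any 1 of 5 arrays: control 2, thrombin 8 h 1 or 2, cyclosporin A 3, or cyclosporin A with 8 h thrombin 1 (replicate numbers).

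Probes without a listed gene stood out because they were left out of every gene count: of 14155 that passed the filter, limma called 217 for 2 h of thrombin and 1414 for 8 h.

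For each comparison of a pair of groups, 10 splits of the 6 arrays are too few; the real split was the 1 with as many genes, and the highest other gave 2 genes for 2 h thrombin, 1 for 8 h thrombin in cyclosporin A and 0 for the 6 other comparisons. For the rest, 100 draws were made. For the interactions, 2 draws, the real one included, reached 2606 genes at 2 h (highest other 2766). At 8 h only the real one reached 5822 (highest other 4517). By the 5% set in advance, these shares argue against a random assignment of these arrays. They cannot exclude chance between cultures, because replicates may be technical. The highest other counts came from draws that left 1 pair of groups apart, which points to a structure of the samples. With neither pair of groups left apart, 84 draws gave at most 1 gene at 2 h and 82 gave at most 0 at 8 h. Such draws mix arrays with and without cyclosporin A, which removes every cyclosporin A difference and widens the spread. Their low counts therefore follow by design and do not bear on the interaction itself. Over all 100 draws, the real one included, slopes as low as 0.449 came in 4 (lowest other 0.282). Slopes as low as 0.118 came in 2 (lowest other 0.109). Those shares, under 5%, argue against a random assignment of these arrays, narrowly at 2 h, and against nothing further. For the overlap of both times, 2 draws reached 1058; the highest other, 5924, had all 3 arrays of 8 h thrombin placed as controls, again a structure of the samples, and the remaining draws gave at most 315.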

How the results depend on the processing

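Tests with values as deposited, normexp correction, the filter on the background bound and the fit without the 3 arrays of 8 h thrombin were chosen only after results had been seen; the others were planned.

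A fold of at least 2 left 71 genes for 2 h thrombin, 744 for 8 h, 625 between the times, 84 for cyclosporin A alone, 12 and 614 for cyclosporin A at 2 h and 8 h, 83 and 35 for thrombin in cyclosporin A, 84 and 634 interactions, and an overlap of 33; these fell by construction. The 2 h slope became 0.583 with that threshold and 0.351 after scaling to the 75th percentile; the cause was not tested. The count for cyclosporin A at 2 h was the least stable, at 4597 after that scaling and 6852 as deposited; the cause was not tested. List calls went from 113 of 300 to 44 with an estimated correlation and 178 with fry. Quantile normalization, listed as an alternative, is the main setting and was not run again. Without the 3 arrays of 8 h thrombin, 1530 genes were called for 2 h thrombin. No named gene or list called in the main setting was called in the opposite direction under an alternative, and 96.6% of 24605 gene comparisons and 95.8% of 6220 list comparisons kept their call. The gene comparisons cover named genes and list members with the smallest p, a choice that favours kept calls. Over all called genes, scaling to the 75th percentile kept 1109 of 1623 for 2 h thrombin and 6698 of 7248 for 8 h. It kept 901 of 1297 for cyclosporin A at 2 h and 1642 of 2606 interactions at 2 h. With the mean of a gene's probes some calls reversed, 8 for 8 h thrombin and 10 for cyclosporin A at 8 h among them. F2R at 8 h, not called at 0.06, was called lower with the mean of its probes, at -0.14.

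Leaving out 1 array gave 1113 to 1422 genes (2 h thrombin), 6809 to 6911 (8 h), 6338 to 6549 (between times), 3571 to 3687 (cyclosporin A alone), 829 to 1179 and 6316 to 6440 (cyclosporin A at 2 h and 8 h), 3115 to 3275 and 1658 to 1936 (thrombin in cyclosporin A), 2204 to 2554 and 5458 to 5641 (interactions). The overlap ran from 685 to 1019, slopes from 0.401 to 0.491 and 0.104 to 0.143, and list calls from 110 to 118.

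With the replicate number as a block, 1596 genes were called for 2 h thrombin, 7218 for 8 h and 1265 for cyclosporin A at 2 h. Pairing by that number found little basis: 4 of 45 same-number pairs correlated above 0.1, with 9 of 18 arrays closest to their own number.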

Other observations

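No tests in this part were chosen after a result was seen; all lists and genes follow the rules set in advance.

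Stress and defence genes moved in several directions. Heat shock genes rose in 10 of 12 after 8 h of thrombin with 0 falls, the same adjusted over the list alone, HSPH1 by 2.03 and HSPA8 by 1.18 (limma camera adjusted p = 6.42e-06, but adjusted p = 0.151 with an estimated correlation). Interferon response genes fell in 8 of 15 with 0 rises, also adjusted over the list alone, with IFIT2 at -1.65 and IFIT1 at -1.35 (0.04 on its other probe) (limma camera adjusted p = 0.00315, but adjusted p = 0.128 with an estimated correlation). Of 11 NRF2 and oxidative stress genes, 8 fell and 2 rose, the same adjusted over the list alone; TXNRD1, encoding thioredoxin reductase, changed by -2.34 and HMOX1, encoding haem oxygenase 1, by -1.40 (limma camera adjusted p = 0.00541, but adjusted p = 0.17 with an estimated correlation). In cyclosporin A, 8 h of thrombin lowered 4 of 7 Notch pathway genes and raised 0, likewise adjusted over the list alone, with NOTCH1 at -0.59 and HEY1 at -0.54 (-0.03 on its other probe) (limma camera adjusted p = 0.000974, but adjusted p = 0.107 with an estimated correlation).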
